A study of Mus musculus with 25 samples.

How the data were processed

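PolyA RNA from the medial prefrontal cortex of 5xFAD mice and their WT littermates was measured by bulk RNA sequencing in 25 libraries, 1 per mouse. Per the labels' protocols, AAV2/5 carrying mCherry or iβARK-mCherry was injected at 3 to 4 months of age, tissue was taken 45 days later, RNA had a RIN above 7, and libraries were made with a directional kit and read on a NovaSeq 6000. The groups are male WT mCherry (4), male 5xFAD mCherry (4), male 5xFAD iβARK (3), female WT mCherry (5), female 5xFAD mCherry (5) and female 5xFAD iβARK (4). The deposited file holds raw counts, whole numbers for 55291 gene symbols in 25 columns, and no column belongs to another sample. The counts were made by the authors with fastp 0.23.2, Bowtie2 2.4.5, HISAT2 2.2.1 and RSEM against GRCm38, and DESeq2 1.32.0 is also named, per the submitters' processing notes. Which aligner fed the counts, the strand setting and the annotation are not given in the sources used here, so reads of a gene and of an overlapping or antisense gene may not be told apart.

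Depth was 45234060 to 71937315 counts per library. Gene coordinates came from GENCODE M21 on GRCm38, which matched 96.4 percent of the symbols and 99.2 percent of the reads, and 41 symbols stand for more than 1 gene there. A total of 17017 genes had 0 counts in all libraries. Genes were kept by filterByExpr on the 6 groups (minimum count 10, minimum total 15), leaving 20971.

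The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with TMM scaling and 1 mean per group. The residual degrees of freedom were 19 and the prior degrees of freedom 5.09. Adjusted p-values are Benjamini-Hochberg over the tested genes of 1 comparison, with a threshold of 0.05 and no fold limit. Averaged comparisons are the mean of the male and female contrasts, and sex differences are the female minus the male effect. Standard errors were derived from the same fits. Log2 CPM used a prior count of 2. Folds against a group with 0 counts in every library are given as a floor, with 3 counts placed in that group.

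Gene lists were tested with camera (preset correlation 0.01, adjusted over the 33 lists of 1 comparison), and again with camera with an estimated correlation and with fry. Counts of members are given after adjustment over all genes and after adjustment over the list alone. The 33 lists were plaque-associated microglia, homeostatic microglia, complement, antigen presentation, interferon response, cytokines and chemokines, reactive astrocytes, astrocyte markers, Gq and calcium signalling in astrocytes, immediate early genes, glutamatergic neurons, GABAergic neurons, synaptic genes, oligodendrocytes, oligodendrocyte precursors, endothelium, pericytes and smooth muscle, meningeal fibroblasts, choroid plexus and ependyma, striatal neurons, red cells and neutrophils, lymphocytes, lysosome, mitochondrially encoded genes, nuclear respiratory chain, ribosomal proteins, glycolysis, cholesterol synthesis, heat shock and unfolded protein response, glucocorticoid response, circadian clock, X-linked genes with a Y copy or escape, and AAV and mechanical injury. A list of plasma cell and immunoglobulin constant region genes was added after seeing the data.

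The comparisons, the lists, the tests and the rule for named genes were chosen before the data were examined. Named genes are the label checks (Grk2, Thy1, App, Xist and Y genes), the 10 risers and 10 fallers with the smallest p in the averaged 5xFAD and iβARK comparisons, 5 each way in the other comparisons, and up to 4 members with the smallest p of each described list. Predicted gene models were counted and not named, and some genes that the rule picks are not reported here. Slfn5 and the immunoglobulin and T cell genes outside this rule were picked after seeing the data.

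Both the 5xFAD and the iβARK effect use the 5xFAD mCherry libraries. Their correlation was therefore set beside 50 simulations of groups without effects, and was repeated in 20 draws that divide those libraries between the comparisons. For each comparison the libraries were also regrouped at random within the labels, up to 100 times, and tested in the same way.

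The alternatives planned beforehand were DESeq2 size factors, library totals, no filter, a stricter filter (CPM of 1 in every library of a group), the DESeq2 Wald test (DESeq2 1.42.0), limma voom with sample weights, only the groups compared, 1 surrogate variable (sva 3.50.0), the replicate number as a block, and each library left out in turn. Chosen after seeing the data were leaving out the 3 libraries richest in striatal transcripts, leaving out the 2 iβARK libraries richest in Igkc, oligodendrocyte and striatal scores as covariates, and offsets for GC content and gene length, which were available for 97.9 percent of the tested genes.

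The main script was tested on simulated counts with 67, 67 and 66 genes changed by 1.5, 2 and 4-fold among 20559 to 20573. It recovered 83.6, 97 and 98.5 percent of them for the averaged 5xFAD comparison, 62.7, 88.1 and 97 percent for males, and 68.7, 89.6 and 98.5 percent for females. For the iβARK comparison these were 79.1, 95.5 and 100 percent averaged, 56.7, 85.1 and 95.5 percent in males, and 58.2, 91 and 97 percent in females, and for the sex difference in the 5xFAD effect 49.3, 79.1 and 95.5 percent. False calls made up 1.1 to 6 percent of the calls. Of 33 unchanged lists 1 was called, and a changed list of 30 genes was called. The changed genes were taken from the more highly counted genes only, so the recovery holds for those. Each gene was drawn independently of the others. The simulation thus lacks the correlation between genes and the tissue differences of the real libraries, and false calls may be more frequent there.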

Results

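RNA of the medial prefrontal cortex was sequenced from 25 mice in 6 groups. There were 4 male and 5 female wild-type (WT) mice with an mCherry virus, 4 male and 5 female 5xFAD mice with the same virus, and 3 male and 4 female 5xFAD mice with an iβARK-mCherry virus. Per the labels' protocols, AAV2/5 was injected at 3 to 4 months of age and tissue was taken 45 days later. The deposited file holds whole-number counts for 55291 gene symbols, and the column totals run from 45234060 to 71937315. iβARK is a peptide made from a part of the kinase Grk2, and it holds back signalling through Gq-coupled receptors. No group received an inactive form of it, so an effect of the peptide and a reaction to its construct are not separable in this design.

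The sex and genotype labels were checked first. Xist, the RNA that silences 1 X chromosome, ran from 459 to 997 CPM in the 14 female libraries and from 0.0336 to 0.214 CPM in the 11 male libraries, and Ddx3y, a gene of the Y chromosome, from 44.6 to 60.4 CPM in the males. The 5xFAD mice carry human APP driven by Thy1 promoter sequence. Transgene reads were not counted here, so mouse Thy1 and App serve only as a proxy. Thy1 and App were each higher in all 9 5xFAD mCherry libraries than in every WT library. Thy1 averaged 537 ± 78.6 CPM (mean ± SD) in male WT, 2772 ± 230 in male 5xFAD mCherry and 1360 ± 155 in male iβARK libraries, and 717 ± 58.6, 3152 ± 644 and 2249 ± 296 in the female groups. App averaged 2265 ± 204, 3066 ± 295 and 2453 ± 41.2 CPM in males and 2259 ± 175, 3937 ± 302 and 3290 ± 459 in females. Grk2, whose fragment the virus carries, stayed between 304 and 323 CPM in all 6 group means.

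**Figure D1:**
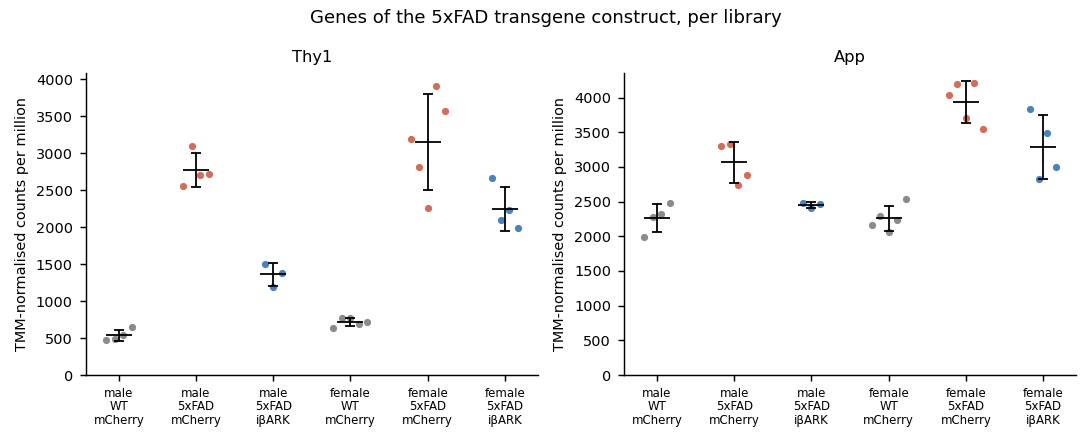
Thy1 and App in each library. The vertical axis is CPM after TMM scaling, the horizontal axis the 6 groups (male and female WT mCherry, 5xFAD mCherry, 5xFAD iβARK). Each point is 1 library, bars are mean ± SD, and all 9 5xFAD mCherry libraries lie above all WT libraries.

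What does the 5xFAD genotype do to the cortex when both sexes are averaged (9 against 9 libraries)? Genes of the plaque-associated microglia list were among the leading risers. Ccl6, a chemokine of myeloid cells (chromosome 11, 83587882 to 83593087, GRCm38), rose by 4.66 ± 0.19 (log2 fold change ± SE, edgeR adjusted p = 3.3e-14), and Itgax, the CD11c integrin (chromosome 7, 128129547 to 128150657), by 6.57 ± 0.31 (2.2e-13). Cst7, an inhibitor of lysosomal cathepsins (chromosome 2, 150570415 to 150578944), rose by 8.34 ± 0.42 (8.4e-13), Trem2, the lipid receptor that drives this state (chromosome 17, 48346401 to 48354147), by 3.27 ± 0.17 (1.6e-12), and Clec7a, a receptor for fungal glucans (chromosome 6, 129461591 to 129472779), by 5.88 ± 0.35 (2.1e-11). Further leading risers were Thy1, a neuronal surface protein and the source of the transgene promoter (chromosome 9, 44043384 to 44048579), by 2.25 ± 0.09 (3.3e-14), Slc15a3, a lysosomal peptide carrier, by 3.05 ± 0.16, Mpeg1, a pore protein of phagocytes, by 3.27 ± 0.18, and St14, a membrane protease, by 3.84 ± 0.23. App, the amyloid precursor (chromosome 16, 84949685 to 85173766), rose by 0.62 ± 0.07 (2.6e-07), while Grk2 moved by 0.08 ± 0.05 (0.31).

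Which genes fell most clearly? Klf11, a zinc finger repressor, fell by 0.48 ± 0.07 on the log2 scale (edgeR adjusted p = 1.4e-05), Pou2f1, a POU factor, by 0.53 ± 0.08, and Sp4, a factor of neurons, by 0.39 ± 0.07. Utp14b, a ribosome assembly gene, fell by 0.54 ± 0.08, Prtg, a cell adhesion gene, by 0.78 ± 0.12, Creb5, a CREB-family factor, by 1.06 ± 0.17, and Ranbp3l, an exporter of Smad proteins, by 0.77 ± 0.13. Apold1, an endothelial immediate early gene, fell by 0.86 ± 0.14, Trim67, a neuronal ubiquitin ligase, by 0.49 ± 0.08, and Dusp1, a phosphatase induced by activity (chromosome 17, 26505590 to 26562128), by 0.58 ± 0.10 (0.00025). In the test, 2095 of 20971 genes passed, 1255 higher and 840 lower, and 441 and 146 of them by more than 2-fold. With library totals in place of TMM the split was 1022 and 1158, and with GC content and length offsets 960 and 933, so the surplus of risers depends on the scaling.

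Gene lists describe the same 18 libraries by cell type and process, and 19 of 33 lists passed camera, 13 higher and 6 lower. Fry called 17, of which 13 were higher and 4 lower. With oligodendrocyte and striatal scores as covariates camera called 15 higher and 3 lower. In plaque-associated microglia 28 of 30 genes rose (29 when adjusted over the list alone, median 2.23), with Spp1, a secreted ligand of these cells, at 3.26 ± 0.25. In homeostatic microglia 12 of 14 rose (12 alone, median 1.12), among them the receptor Gpr34 by 1.77 ± 0.14. In complement 9 of 13 rose (9 alone, median 1.36), with the receptor C3ar1 at 2.79 ± 0.19 and C1qa, a start point of the classical pathway, at 2.10 ± 0.19. In the lysosome list 25 of 30 rose (26 alone, and 1 fell alone, median 0.68), with the protease Ctsd at 2.34 ± 0.15 and the mannosidase Man2b1 at 1.75 ± 0.11. In cytokines and chemokines 9 of 21 rose and 1 fell (10 and 1 alone, median 1.09), with the chemokine Ccl3 at 6.77 ± 0.42 and Tgfb1, a brake on microglia, at 1.66 ± 0.16. These 5 lists also passed with an estimated correlation, at adjusted p = 4.4e-05, 0.00096, 0.0026, 6.2e-05 and 0.0054.

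The next 8 lists were higher in camera and in fry, and did not pass with an estimated correlation. In antigen presentation 10 of 18 rose (15 alone, median 0.97, adjusted p = 0.29 with an estimated correlation), with B2m, the light chain of MHC class I, at 1.33 ± 0.20. In the interferon response 7 of 30 rose (13 alone, median 0.64, adjusted p = 0.40 with an estimated correlation), with the secreted glycoprotein Lgals3bp at 1.99 ± 0.21. In reactive astrocytes 14 of 32 rose and 2 fell (17 and 3 alone, median 0.46, adjusted p = 0.096 with an estimated correlation). Gfap, the intermediate filament of reactive astrocytes, rose by 2.73 ± 0.20 and Serpina3n, a secreted protease inhibitor, by 2.04 ± 0.23. In cholesterol synthesis 13 of 23 rose (15 alone, median 0.26, adjusted p = 0.096 with an estimated correlation), with the dehydrogenase Nsdhl at 0.67 ± 0.07 and squalene synthase Fdft1 at 0.39 ± 0.05. In glycolysis 7 of 20 rose and 1 fell (11 and 1 alone, median 0.16, adjusted p = 0.24 with an estimated correlation), with the lactate carrier Slc16a3 at 1.15 ± 0.14. In ribosomal proteins 36 of 76 rose (65 alone, median 0.23, adjusted p = 0.37 with an estimated correlation) and in the nuclear respiratory chain 13 of 67 (23 alone, median 0.14, adjusted p = 0.40 with an estimated correlation). In AAV and mechanical injury 5 of 21 rose and 2 fell (6 and 3 alone, median 0.15, adjusted p = 0.40 with an estimated correlation), and its camera call was lost without male WT replicate 3 (adjusted p = 0.0607).

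Among the 6 lower lists, 11 of 27 immediate early genes fell and 1 rose (14 and 1 alone, median -0.33, adjusted p = 0.32 with an estimated correlation). Btg2, an antiproliferative gene induced by activity, fell by 0.74 ± 0.15 and the kinase Sik1 by 0.53 ± 0.11. In GABAergic neurons 3 of 22 fell (5 fell and 1 rose alone, median -0.16, adjusted p = 0.33 with an estimated correlation), with the neuregulin receptor Erbb4 down by 0.34 ± 0.07. The other 4 are lists of further cell types, and the source of their falls was not tested. In striatal neurons 11 of 19 fell (17 alone, median -1.20, adjusted p = 0.40 with an estimated correlation), with the striatal factor Isl1 down by 3.94 ± 0.91. In oligodendrocytes 1 of 22 fell (13 alone, median -0.43, adjusted p = 0.42 with an estimated correlation), in meningeal fibroblasts 8 of 20 fell and 1 rose (11 and 1 alone, median -0.65, adjusted p = 0.40 with an estimated correlation), and in choroid plexus and ependyma 2 of 14 fell (6 alone, median -0.42, adjusted p = 0.40 with an estimated correlation). The choroid plexus call was lost without male WT replicate 2 (adjusted p = 0.0679) and without female WT replicate 1 (0.0638). Male WT 1 and female WT 2 had striatal scores of 5.71 and 4.42 against 1.81 to 3.63 in 22 of the other libraries.

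The remaining 14 lists did not pass in the genotype comparison. Members changed in astrocyte markers in 3 of 23 (4 alone, median 0.03), in Gq and calcium signalling in astrocytes in 5 of 37 (3 up, 2 down; 4 and 2 alone, median -0.03), in glutamatergic neurons in 4 of 18 (2 up, 2 down; 4 and 4 alone, median 0.08), and in synaptic genes in 1 of 34 (1 alone, median 0.04). Grm3, a glutamate receptor of astrocytes, fell by 0.36 ± 0.06 and Adra1b, a Gq-coupled noradrenaline receptor, rose by 0.41 ± 0.08. For oligodendrocyte precursors 1 of 15 fell (1 alone, median -0.14), for endothelium and for pericytes and smooth muscle 0 of 18 and 0 of 12 passed edgeR (0 and 0 alone, medians -0.06 and -0.12), and for mitochondrially encoded genes 0 of 8 (0 alone, median 0.09). For red cells and neutrophils 1 of 8 rose (1 alone), with a median of -0.09 beside a mean of 0.63 and a camera direction of lower. For lymphocytes 1 of 20 fell (0 alone, median 0.02), for heat shock and the unfolded protein response 2 of 26 rose and 2 fell (2 and 2 alone, median 0.06), for the glucocorticoid response 5 of 16 rose and 1 fell (6 and 1 alone, median 0.14), for the circadian clock 2 of 18 rose (2 alone, median 0.02), and for X-linked genes with a Y copy or escape 1 of 6 fell (1 alone, median -0.07). Fkbp5, a glucocorticoid target, rose by 0.65 ± 0.14 and Bhlhe41, a clock repressor, by 0.44 ± 0.07.

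**Figure D2:**
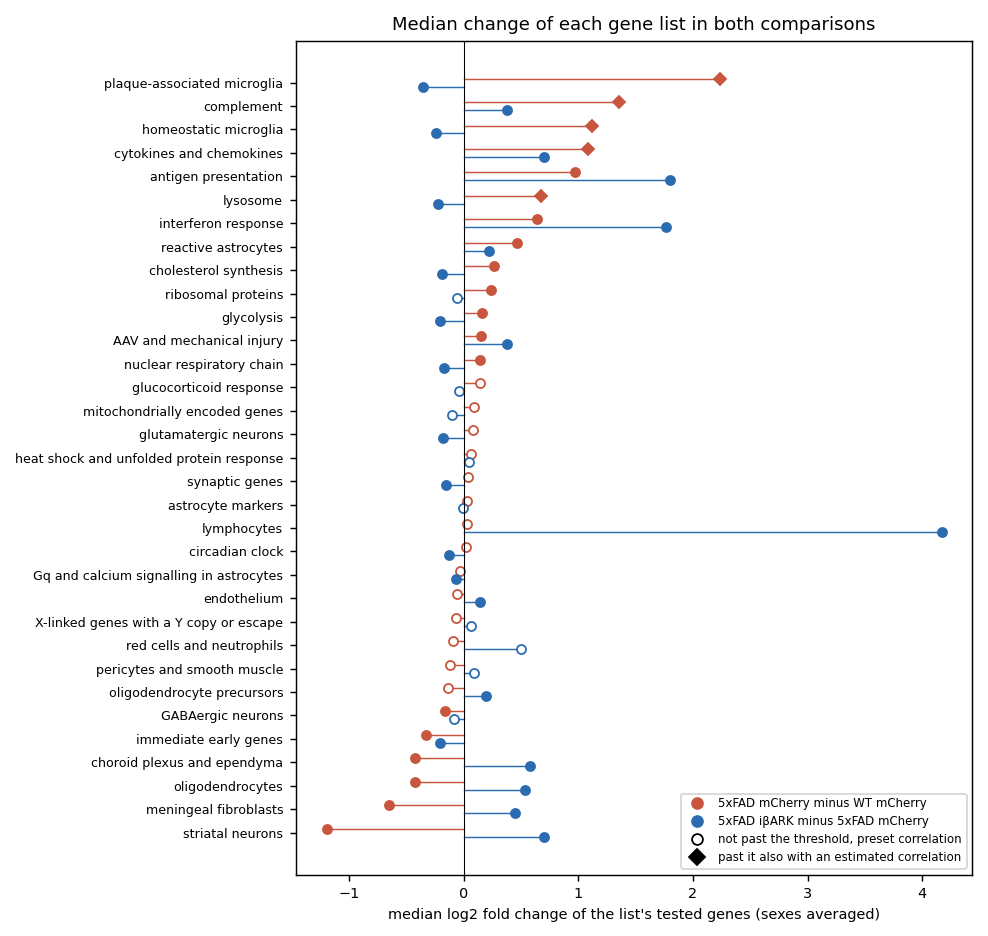
Median log2 fold change (horizontal axis) of the 33 gene lists (vertical axis) with the sexes averaged. Red marks 5xFAD mCherry minus WT mCherry, blue marks 5xFAD iβARK minus 5xFAD mCherry. Open marks did not pass camera, and diamonds passed also with an estimated correlation. No error bars are drawn. Plaque-associated microglia sit at 2.23 in red and -0.35 in blue.

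Is the genotype effect present in each sex? Among males (4 against 4), Thy1 rose by 2.37 ± 0.14 (edgeR adjusted p = 1.4e-10), the chemokine Ccl6 by 4.71 ± 0.29, the integrin Itgax by 6.36 ± 0.45, the cathepsin inhibitor Cst7 by 8.04 ± 0.60 and the receptor Trem2 by 3.32 ± 0.25. Among females (5 against 5), Ccl6 rose by 4.62 ± 0.26 (3.3e-11), Thy1 by 2.14 ± 0.13, Itgax by 6.77 ± 0.41 and the peptide carrier Slc15a3 by 3.52 ± 0.22. App rose by 0.44 ± 0.10 in males and 0.80 ± 0.09 in females. Plaque-associated microglia rose in both sexes, with 24 of 30 genes up in males (27 alone, median 2.18) and 26 of 30 in females (28 alone, median 2.38). In the respiratory chain 56 of 67 genes were up in males (60 alone, median 0.40, adjusted p = 0.096 with an estimated correlation) and 0 in females (0 alone, median -0.10, adjusted p = 0.67 with an estimated correlation).

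Which genes fell in each sex? In males Tob2, an antiproliferative gene (chromosome 15, 81848272 to 81858796), fell by 0.68 ± 0.09 (edgeR adjusted p = 5.5e-05), the ribosome assembly gene Utp14b by 0.86 ± 0.13, the POU factor Pou2f1 by 0.77 ± 0.12, the matrix protease Adamts1 by 0.92 ± 0.14 and the acetyltransferase Kat6a by 0.47 ± 0.08. None of the 5 passed in females, and the sex difference was 0.66 ± 0.13 for Tob2 (0.017), 0.63 ± 0.17 for Utp14b (0.049), 0.49 ± 0.15 for Pou2f1 (0.086), 0.77 ± 0.19 for Adamts1 (0.036) and 0.50 ± 0.10 for Kat6a (0.018). In females Nppc, a natriuretic peptide, fell by 0.84 ± 0.14, the adaptor Sh2d3c by 0.53 ± 0.10 and the AP-1 factor Jun by 0.74 ± 0.14, with sex differences of -1.27 ± 0.21 (0.013), -0.48 ± 0.14 (0.07) and -0.51 ± 0.20 (0.18). Klf11 fell by 0.48 ± 0.09 and Dusp1 by 0.70 ± 0.13 in females, and both fell in males too. In the test 2413 genes passed in males (1469 higher, 944 lower) and 907 in females (780 higher, 127 lower). With GC content and length offsets the splits were 764 and 739 in males and 711 and 233 in females. The male count was 1059 without male WT replicate 2, 1560, 1524 and 1284 without male 5xFAD mCherry replicates 2, 3 and 4. The sexes shared 416 risers (54.6 expected by chance) and 16 fallers (5.72 expected).

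Does the genotype effect itself differ by sex (18 libraries)? Among the genes with a lower effect in females, Dmac1, an assembly factor of complex I, differed by -0.77 ± 0.12 (female minus male effect, edgeR adjusted p = 0.013), Cox14, an assembly factor of complex IV, by -0.70 ± 0.12, and the mitochondrial ribosome genes Mrpl20 and Mrps18a by -0.76 ± 0.13 and -0.54 ± 0.09. Thy1 (-0.23 ± 0.18, 0.57) and App (0.36 ± 0.13, 0.13) did not pass. Higher in females were Tab2, an adaptor of TNF signalling, by 0.48 ± 0.10, Snx29, a sorting nexin, by 0.66 ± 0.13, and Pcdhga8, a clustered protocadherin, by 0.77 ± 0.16. In the nuclear respiratory chain 35 of 67 genes were lower (59 alone, median -0.49, adjusted p = 0.15 with an estimated correlation), and ribosomal proteins and glycolysis were lower in camera with 0 members past edgeR (medians -0.28 and -0.18, adjusted p = 0.94 and 0.94 with an estimated correlation). Oligodendrocytes (0 of 22, 16 alone, median 0.92) and their precursors (median 0.37) were higher in camera (adjusted p = 0.94 and 0.94 with an estimated correlation).

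The count of this interaction moved by more than 1.5 times without any 1 of 13 of the 18 libraries. In the test 506 genes passed (110 higher, 396 lower; 163 and 320 with DESeq2 size factors), and 0 without the 3 libraries richest in striatal transcripts, a set chosen after seeing the data. With GC content and length offsets 80 genes passed, and the respiratory chain median went from -0.49 to -0.24 with 6 of 67 genes lower. The count was 293, 15, 265 and 1148 without male WT replicates 1 to 4, 189, 68 and 104 without male 5xFAD mCherry replicates 2 to 4, 127, 104 and 214 without female WT replicates 2 to 4, and 148, 47 and 303 without female 5xFAD mCherry replicates 1 to 3. Without male WT replicate 2 the adjusted p of Tob2, Tab2, Snx29 and Pcdhga8 was 0.061 each, and Tab2 stood at 0.0511 without female 5xFAD mCherry replicate 2. The WT groups carry part of the result. Between WT females and males (5 against 4) 48 of 67 respiratory chain genes were already higher in females (64 alone, median 0.34, adjusted p = 0.43 with an estimated correlation).

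What does iβARK change in the 5xFAD cortex, sexes averaged (7 against 9)? Antibody and interferon genes led the risers. Ighv1-26, a heavy chain variable segment (chromosome 12, 114788372 to 114788805), rose at least 492-fold in males, where the controls had 0 counts (edgeR adjusted p = 4e-07 with the sexes averaged), the joining chain Jchain (chromosome 5, 88519809 to 88527891) by a log2 fold change of 7.05 ± 0.89 and the IgG2b constant region Ighg2b (chromosome 12, 113302965 to 113307933) by 6.62 ± 0.85. Interferon-induced GTPases followed, with Gbp5 (chromosome 3, 142493978 to 142522344) at 2.46 ± 0.30 (0.00012), Gbp6 (chromosome 5, 105270702 to 105293698) at 3.34 ± 0.41, Gbp7 (chromosome 3, 142530342 to 142550149) at 1.87 ± 0.24, Gbp3 at 2.07 ± 0.27 and Irgm2 at 2.32 ± 0.31, beside Nlrc5, the activator of MHC class I (chromosome 8, 94434356 to 94527272), at 3.03 ± 0.38 and the antiviral gene Oasl2 at 2.75 ± 0.36. Ighv1-26 and Ighg2b were higher in 7 of 7 iβARK libraries than in all 9 5xFAD mCherry libraries, and Jchain in 6 of 7. Reads shared within the immunoglobulin and Gbp families make the split between their members uncertain.

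Thy1 led the fallers, by 0.76 ± 0.10 on the log2 scale (edgeR adjusted p = 0.00013), with 6 of 7 iβARK libraries below all 9 5xFAD mCherry libraries. App fell by 0.29 ± 0.07 (0.018; 3 of 7 libraries below all 9), and its call was lost without male iβARK replicate 2 (0.0618) and without female iβARK replicate 4 (0.0522), with 1 surrogate variable (-0.21, 0.288), with tissue covariates (-0.22, 0.197) and without the 3 libraries richest in striatal transcripts (-0.26, 0.0505). Ccl6 fell by 1.20 ± 0.17, Fcrls, a microglial Fc receptor-like gene, by 1.39 ± 0.21 and Trem2 by 0.82 ± 0.17. Fkbp1b, a brake on calcium release channels (chromosome 12, 4833174 to 4841591), fell by 0.48 ± 0.07, Nrsn1, a vesicle protein of neurons, by 0.30 ± 0.05, Bend6, a neuronal corepressor, by 0.32 ± 0.05, Rnf208, a ubiquitin ligase, by 0.31 ± 0.05 and Mettl27, a methyltransferase, by 0.49 ± 0.08. The cholesterol genes Fdft1 and Nsdhl fell by 0.39 ± 0.05 and 0.44 ± 0.07. Grk2 moved by -0.06 ± 0.05 (0.47).

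In the test 1157 genes passed, 631 higher and 526 lower, with 358 and 23 past 2-fold. DESeq2 size factors gave 671 and 349, and library totals 1123 and 136, so the number of fallers depends on the scaling. With 1 surrogate variable 169 were higher and 29 lower, with the replicate block 214 and 98, and with tissue covariates 277 and 85. The count was 709 and 661 without male 5xFAD mCherry replicates 1 and 2, 2206 and 537 without male iβARK replicates 1 and 2, 744 and 640 without female 5xFAD mCherry replicates 3 and 4, and 509 without female iβARK replicate 4.

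Of 33 lists, 24 passed camera for iβARK, 13 higher and 11 lower, and 0 passed with an estimated correlation, while fry called 13. In the interferon response 29 of 30 genes rose (29 alone, median 1.76, adjusted p = 0.074 with an estimated correlation), with Ifi44 at 2.83 ± 0.38. In antigen presentation 16 of 18 rose (17 alone, median 1.80, adjusted p = 0.078 with an estimated correlation), with the peptide carrier Tap1 at 2.30 ± 0.32, the class I gene H2-K1 at 1.94 ± 0.28 and the class II gene H2-Eb1 at 4.88 ± 0.71. In lymphocytes 18 of 20 rose (18 alone, median 4.17, adjusted p = 0.14 with an estimated correlation), with the T cell coreceptor Cd8a at 4.25 ± 0.69 and Nkg7, a granule protein of killer cells, at 4.90 ± 0.85. Without the 2 iβARK libraries richest in Igkc, 6 of 17 lymphocyte genes were higher and 1 lower (median 2.03), and the calls of the cytokine and complement lists were lost. In cytokines and chemokines 6 of 21 rose and 1 fell (11 and 2 alone, median 0.70, adjusted p = 0.26 with an estimated correlation), with Ccl5 at 5.17 ± 0.73 and Cxcl9, a draw for T cells, at 6.72 ± 1.06. Cxcl9 averaged 0.0199 CPM in male and 0.117 CPM in female 5xFAD mCherry libraries, so the size of its rise is uncertain. In AAV and mechanical injury 7 of 21 rose (9 alone, median 0.37, adjusted p = 0.14 with an estimated correlation). In reactive astrocytes 7 of 32 rose (8 up and 1 down alone, median 0.22, adjusted p = 0.26 with an estimated correlation), with the class I gene H2-D1 at 1.71 ± 0.25. Gfap, also in that list, had lower means with iβARK than in 5xFAD mCherry libraries. It went from 915 ± 162 to 616 ± 57.4 CPM in males (mean ± SD). In females it went from 1369 ± 502 to 1100 ± 397 CPM. The ranges overlapped in both sexes, in males only narrowly (679 to 1047 CPM with mCherry and 571 to 681 with iβARK). Whether the rise of the list goes beyond its immune genes such as H2-D1 was not tested. In complement 3 of 13 rose (5 alone, median 0.38, adjusted p = 0.49 with an estimated correlation), led by C3, the central component, at 4.83 ± 0.79. The cytokine, reactive astrocyte and complement lists did not pass in fry. The complement call was lost without male 5xFAD mCherry replicate 1 (adjusted p = 0.115), male iβARK replicate 1 (0.353), female 5xFAD mCherry replicate 3 (0.0803) and female iβARK replicates 1 (0.102) and 4 (0.0867).

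Lists of microglia and metabolism were lower under iβARK. In plaque-associated microglia 12 of 30 fell and 1 rose (14 and 2 alone, median -0.35, adjusted p = 0.26 with an estimated correlation), with the adaptor Tyrobp down by 1.07 ± 0.21 and B2m up by 1.06 ± 0.21. In the lysosome list 14 of 30 fell (17 alone, median -0.22, adjusted p = 0.13 with an estimated correlation), with the galactosidase Glb1 down by 0.45 ± 0.08 and Ctsd by 0.74 ± 0.15. In homeostatic microglia 2 of 14 fell (6 fell and 1 rose alone, median -0.24, adjusted p = 0.34 with an estimated correlation). In cholesterol synthesis 7 of 23 fell (13 alone, median -0.19, adjusted p = 0.13 with an estimated correlation), in glycolysis 9 of 20 (12 fell and 1 rose alone, median -0.21, adjusted p = 0.13 with an estimated correlation), with the neuronal enolase Eno2 down by 0.30 ± 0.06, and in the nuclear respiratory chain 8 of 67 (25 alone, median -0.17, adjusted p = 0.26 with an estimated correlation). Further lists were lower as well. In immediate early genes 5 of 27 fell (8 alone, median -0.21, adjusted p = 0.26 with an estimated correlation), in synaptic genes 4 of 34 (10 alone, median -0.16, adjusted p = 0.26 with an estimated correlation), in glutamatergic neurons 2 of 18 (3 alone, median -0.18, adjusted p = 0.23 with an estimated correlation) and in the circadian clock 3 of 18 (5 alone, median -0.13, adjusted p = 0.13 with an estimated correlation). In Gq and calcium signalling in astrocytes 2 of 37 fell and 1 rose (8 and 1 alone, median -0.06, adjusted p = 0.29 with an estimated correlation), with the muscarinic receptor Chrm3 down by 0.54 ± 0.11. The synaptic and glutamatergic calls were lost with oligodendrocyte and striatal scores as covariates (adjusted p = 0.0634 and 0.0685). The calls for both microglial lists and for immediate early genes did not pass in fry. The Gq call did not pass in fry, was lost with these covariates and without the 2 Igkc-rich libraries, and was also lost without male 5xFAD mCherry replicate 1 (adjusted p = 0.0786), male iβARK replicate 1 (0.0764) and female iβARK replicate 2 (0.0802).

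Lists of other cell types were higher, and whether this reflects tissue from outside the cortex was not tested. In oligodendrocytes 1 of 22 rose (22 alone, median 0.53, adjusted p = 0.26 with an estimated correlation), in their precursors 2 of 15 (2 alone, median 0.20, adjusted p = 0.26 with an estimated correlation), in meningeal fibroblasts 1 of 20 (8 alone, median 0.44, adjusted p = 0.26 with an estimated correlation), and in choroid plexus and ependyma 0 of 14 (2 alone, median 0.58, adjusted p = 0.23 with an estimated correlation). In striatal neurons 0 of 19 rose (5 alone, median 0.70, adjusted p = 0.48 with an estimated correlation), and the camera call was lost without male iβARK replicate 2 (adjusted p = 0.217), whose striatal score was 4.51. In endothelium 2 of 18 rose (2 alone, median 0.14, adjusted p = 0.48 with an estimated correlation), and its call was lost without male iβARK replicate 3 (adjusted p = 0.32). Oligodendrocytes, their precursors, endothelium and striatal neurons did not pass in fry. The other 9 lists did not pass. Pericytes and smooth muscle, red cells and neutrophils, mitochondrially encoded genes, ribosomal proteins, heat shock, the glucocorticoid response, X-linked genes and astrocyte markers had 0 members past edgeR (0 alone each, medians 0.09, 0.50, -0.10, -0.06, 0.04, -0.04, 0.06 and -0.01). In GABAergic neurons 1 of 22 fell (2 fell and 1 rose alone, median -0.08).

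**Figure D3:**
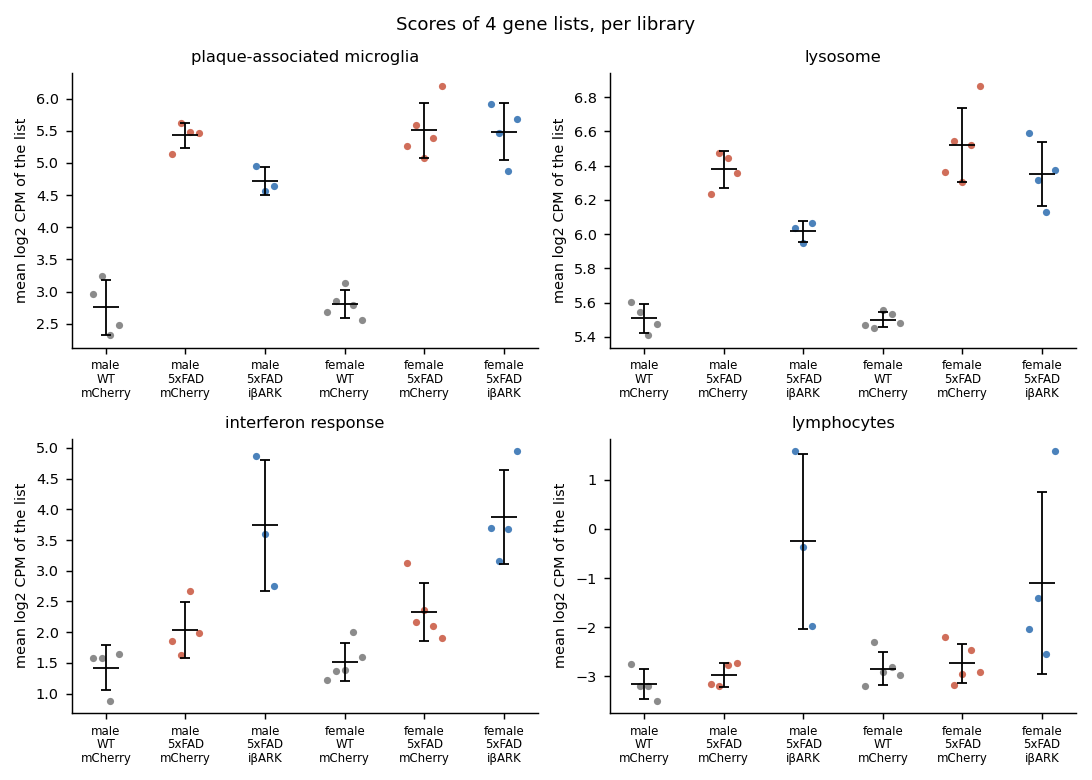
Scores of 4 lists in each library: plaque-associated microglia, lysosome, interferon response and lymphocytes. The vertical axis is the mean log2 CPM of the list, the horizontal axis the 6 groups. Each point is 1 library, and bars are mean ± SD.

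Which antibody genes appeared in the iβARK libraries? Igkc, the kappa constant region, averaged 471 ± 588 CPM (mean ± SD, range 10.2 to 1133) in male and 463 ± 834 CPM (41.7 to 1713) in female iβARK libraries, against 0.429 ± 0.596 to 2.82 ± 5.26 in the other 4 groups. It was above all 5xFAD mCherry libraries in 6 of 7. Of 218 variable genes, 106 had 3 or more counts in some iβARK library and 34 in some other library, and 3 had them in all 7: Igkv6-25 (21562 counts in 7 iβARK libraries, 92 in 18 others), Ighv1-26 (9190 and 37) and Igkv5-39 (24871 and 927). The constant regions split the 7 libraries. Ighg2c, an IgG2c heavy chain, made up 66.8, 67.2 and 77.8 percent of heavy chain counts in male iβARK 1, male iβARK 2 and female iβARK 4, which also had the most Igkc. In a list of plasma cell genes added after seeing the data, 14 of 17 rose (14 alone, median 5.04), which restates the genes that prompted it. Cd8a averaged 2.35 ± 2.06 CPM in male and 1.84 ± 2.79 in female iβARK libraries, against 0.045 to 0.155 in the other group means.

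**Figure D4:**
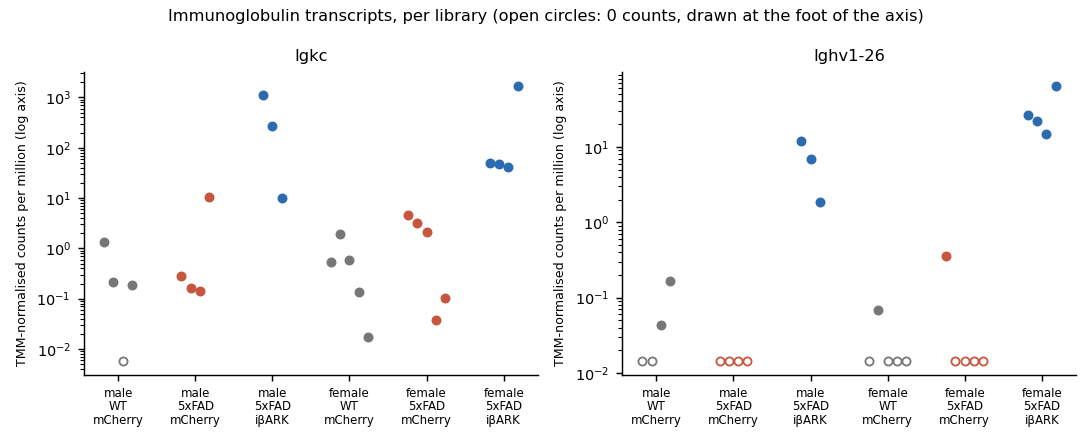
Igkc and Ighv1-26 in each library. The vertical axis is CPM after TMM scaling on a log axis, the horizontal axis the 6 groups, and each point is 1 library. Open circles are libraries with 0 counts, drawn at the foot of the axis. No error bars are drawn.

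Is the iβARK effect present in each sex? In males (3 against 4) Ighv1-26 rose at least 492-fold as given above (edgeR adjusted p = 0.0011), Gbp6 by 3.87 ± 0.63 on the log2 scale, Gbp5 by 2.60 ± 0.45, the MHC activator Nlrc5 by 3.34 ± 0.58 and the kinase Cdc42bpg by 0.94 ± 0.16. Males also showed falls in Fkbp1b by 0.79 ± 0.10, Ccl6 by 1.94 ± 0.27, Mettl27 by 0.88 ± 0.12, Thy1 by 1.03 ± 0.15 and Nrsn1 by 0.48 ± 0.07. In females (4 against 5) Ighv1-26 rose by 8.74 ± 0.81 (1.1e-05), Ighg2b by 7.22 ± 1.12, Jchain by 7.06 ± 1.17, Gbp7 by 1.87 ± 0.31 and Gbp5 by 2.33 ± 0.39. Ighv1-26 ran from 0 to 0.352 CPM in the female 5xFAD mCherry libraries, so the size of its rise is uncertain. The clock gene Per1 fell by 0.44 ± 0.10 (0.046) in females. Of the genes above, Thy1, Ccl6, Fkbp1b, Mettl27, Nrsn1 and Cdc42bpg passed in males alone, with sex differences of 0.54 ± 0.19 (0.82), 1.47 ± 0.34 (0.29), 0.61 ± 0.14 (0.26), 0.78 ± 0.16 (0.26), 0.35 ± 0.09 (0.57) and -0.50 ± 0.21 (0.92). Per1 passed in females alone (sex difference -0.19 ± 0.15, 0.95), and App passed in neither sex (-0.32 ± 0.11, 0.094, and -0.26 ± 0.09, 0.45).

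By list, 25 of 30 interferon genes rose in males (29 alone, median 1.86, adjusted p = 0.21 with an estimated correlation) and 15 of 30 in females (29 alone, median 1.51, adjusted p = 0.04 with an estimated correlation). Plaque-associated microglia had 11 of 30 lower in males (16 lower and 1 higher alone, median -0.58, adjusted p = 0.21 with an estimated correlation), and in females 1 of 30 rose (2 alone, median -0.15) with a camera p that did not pass (0.11). The sex difference of that list had a median of 0.38 and passed camera (8e-09, adjusted p = 0.88 with an estimated correlation). Spp1 was the single gene with a sex difference, at 2.96 ± 0.47 (edgeR adjusted p = 0.035, chromosome 5, 104435118 to 104441050): it rose by 1.64 ± 0.30 in females and fell in males (0.018 and 0.048).

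In the test 580 genes passed in males (302 higher, 278 lower) and 86 in females (84 higher, 2 lower), and 74 rose in both (1.21 expected by chance). The male count was 16 with 1 surrogate variable, 47 with the replicate block and 157 with only the groups compared, and 1 of 34 random regroupings gave 620. The female count was 0 with limma voom and 2 with only the groups compared. With DESeq2 size factors the male split was 320 and 192, and with library totals 427 and 104. The male count was 109, 58 and 145 without male 5xFAD mCherry replicates 1, 2 and 4, and 1753, 173 and 315 without male iβARK replicates 1, 2 and 3. The female count was 2, 7, 1 and 1 without female 5xFAD mCherry replicates 2 to 5, and 144, 138 and 1 without female iβARK replicates 2, 3 and 4. In females Ighg2b, Jchain, Gbp5 and Gbp7 lost their calls without female iβARK replicate 4 (edgeR adjusted p = 0.141 each). The same held without female 5xFAD mCherry replicates 4 and 5 (0.0683 to 0.0792), Jchain, Gbp5 and Gbp7 also without replicate 2 (0.0638 to 0.0661), and Jchain without replicate 3 (0.0559). Per1 lost its call in females without any 1 of female 5xFAD mCherry 1 to 5 and female iβARK 2 to 4 (0.0527 to 0.534). The sex difference of Spp1 lost its call without male 5xFAD mCherry 2, 3 or 4, male iβARK 2 or 3, female 5xFAD mCherry 1, 3, 4 or 5, or female iβARK 1, 2 or 4 (0.0511 to 0.342). The count of sex differences was 14 without male iβARK replicate 1, and 1078 genes had an unadjusted p under 0.05.

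Does iβARK turn the 5xFAD effect back? Of the 1255 genes raised by the genotype 150 fell under iβARK (31.5 expected by chance), and of the 840 lowered 102 rose (25.3 expected). Another 39 rose in both (37.8 expected) and 4 fell in both (21.1 expected). Trem2, Tyrobp, Ccl6, Ctsd, Nsdhl, Fdft1, Thy1 and App are on the first list. Both effects use the same 9 5xFAD mCherry libraries, so some opposition arises by itself. Groups without any effect were therefore simulated against shared libraries. Each gene was drawn independently there, without the correlation between genes and the tissue differences of the real libraries. The simulated spread may therefore be too narrow, also for each sex. The expected overlaps above are n1 × n2 / N, which leave the sharing out. Across 20971 genes r was -0.24 and the covariance -0.0838, against a simulated r of -0.465 and covariance of -0.0397 (SD 0.0018, 50 draws), a difference of -0.0442. That difference depends on the libraries used. The covariance was -0.0404 without the 3 libraries richest in striatal transcripts, where 70 genes were called opposite. It was -0.0671 with tissue covariates and -0.126 without the 2 iβARK libraries richest in Igkc. The simulation was not repeated for these settings. Of the 2095 genotype genes 76.8 percent had the opposite sign (simulated mean 65.2, highest 67.3), and 252 were called in opposite directions (56.8 expected). The simulated share was taken over these same genes without selecting on the simulated genotype effect. Selection on that effect raises the opposition through the shared libraries, so the simulated share is too low for a fair comparison. With the shared libraries divided between the comparisons, r was -0.152 on average (-0.22 to -0.0893 in 20 draws), 59.3 percent had opposite signs (47.1 to 78.0), and 7 to 51 genes (median 27) were called opposite.

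By sex, r in males was -0.398, the covariance -0.219 against a simulated -0.0906, and 235 genes were called in opposite directions (33.1 expected without the sharing). Of the male genotype genes 90 percent had the opposite sign (simulated mean 65.4, which is too low for the same reason). With divided libraries 7 to 36 genes (median 9) were called opposite, and 78.8 percent had opposite signs (57.9 to 92.0). In females r was -0.158, and the covariance of -0.0572 was no further from 0 than the simulated -0.0675. There 2 genes were called opposite (0.583 expected), 1 of them a predicted gene, and 3 (Spp1, Slfn5 and H2-D1) in the same direction. With divided libraries r was -0.226 in males and 0.003 in females, and the difference between the sexes was not tested.

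How far do iβARK mice stand from WT, sexes averaged (7 against 9)? Microglial genes remained high: Itgax by 5.85 ± 0.31 (edgeR adjusted p = 9.6e-12), Ccl6 by 3.46 ± 0.19, Cst7 by 7.27 ± 0.42, Slc15a3 by 2.75 ± 0.17 and Mpeg1 by 2.82 ± 0.18. The 5 leading fallers were members of the immediate early gene list, with Dusp1 lower by 1.03 ± 0.11 (2.3e-07), the AP-1 factors Junb and Fos by 0.92 ± 0.12 and 1.15 ± 0.16, the nuclear receptor Nr4a1 by 0.91 ± 0.13 and Apold1 by 1.11 ± 0.16. Thy1 stood above WT (1.34 ± 0.14 in males and 1.65 ± 0.13 in females), App 0.33 ± 0.07 (0.0024) and Grk2 0.02 ± 0.05. All 30 interferon genes (30 alone, median 2.60) and all 18 antigen presentation genes (18 alone, median 2.83) were higher than in WT, and 16 of 27 immediate early genes were lower and 1 higher (21 and 1 alone, median -0.55). These lists also passed with an estimated correlation (adjusted p = 0.0041, 0.0041 and 0.029). In meningeal fibroblasts, choroid plexus and mitochondrially encoded genes the median and the camera direction pointed to different sides. Mitochondrially encoded genes had a median of -0.01 beside a mean of 0.04, and glycolysis -0.08 beside 0.07. None of these 4 passed.

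In males (3 against 4) Itgax stood 5.06 ± 0.45 above WT (edgeR adjusted p = 9.6e-07), Cst7 6.40 ± 0.61, Ccl6 2.77 ± 0.29, Thy1 as given above and the protease St14 3.11 ± 0.36. Apold1 was lower by 1.64 ± 0.24, the protocadherin Pcdhga8 by 0.78 ± 0.13, Dusp1 by 0.97 ± 0.16, Sytl2, a vesicle docking gene, by 0.55 ± 0.10 and Tob2 by 0.56 ± 0.10. In females (4 against 5) Itgax stood 6.65 ± 0.41 above WT, Ccl6 4.16 ± 0.26, Slc15a3 3.41 ± 0.23 and Cst7 8.13 ± 0.56, with Mpeg1 also among the first 5, while Dusp1, Junb, Nr4a1, Fos and the chromatin reader Phf13 were lower by 1.09 ± 0.14, 1.05 ± 0.16, 0.98 ± 0.17, 1.21 ± 0.22 and 0.47 ± 0.08. App did not pass in males (0.12 ± 0.11, 0.64). In the test 1788 genes passed with the sexes averaged (1369 higher, 419 lower; 1604 and 185 with library totals, 1305 and 943 with GC content and length offsets), 803 in males (657 and 146) and 1363 in females (1108 and 255; 1060 and 614 with the offsets). The male count was 469 without male WT replicate 3 and 457 without male iβARK replicate 1, and the female count 839 without female iβARK replicate 4. Of the genotype risers 735 were also higher here (81.9 expected for independent comparisons) and of the fallers 124 lower (16.8 expected). Both comparisons use the same WT libraries, which raises these overlaps, and the expected values leave that out.

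How do WT females and males differ (5 against 4)? Beside Xist (12.81 ± 0.34), the X-linked Ddx3x and Eif2s3x, which escape silencing, were higher in females by 0.46 ± 0.07 (edgeR adjusted p = 0.0035) and 0.54 ± 0.09, as were Cd83, a surface protein of immune cells, by 0.57 ± 0.10 and Mocs3, a gene of cofactor synthesis, by 0.52 ± 0.09. The Y genes Kdm5d, Ddx3y, Uty and Eif2s3y were read in males alone, and Tob2 was lower in females by 0.80 ± 0.09 (1.1e-05). Of 6 X-linked genes 4 were higher (5 alone, median 0.45, adjusted p = 3.8e-06 with an estimated correlation). With tissue covariates Ddx3x, Eif2s3x, Cd83 and Mocs3 lost their calls (adjusted p = 0.131 to 0.149), the last 3 also without the 3 libraries richest in striatal transcripts (0.0648 each). In oligodendrocytes 13 of 22 were lower in females (21 alone, median -0.87, adjusted p = 0.62 with an estimated correlation), and in immediate early genes 11 of 27 (16 alone, median -0.49, adjusted p = 0.49 with an estimated correlation). In the test 1964 genes passed, 1067 higher and 897 lower. The count was 684, 243, 1307 and 3009 without male WT replicates 1 to 4 and 674, 1288 and 1182 without female WT replicates 2 to 4, and 30 without the 3 libraries richest in striatal transcripts, 2 of which are WT.

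**Figure D5:**
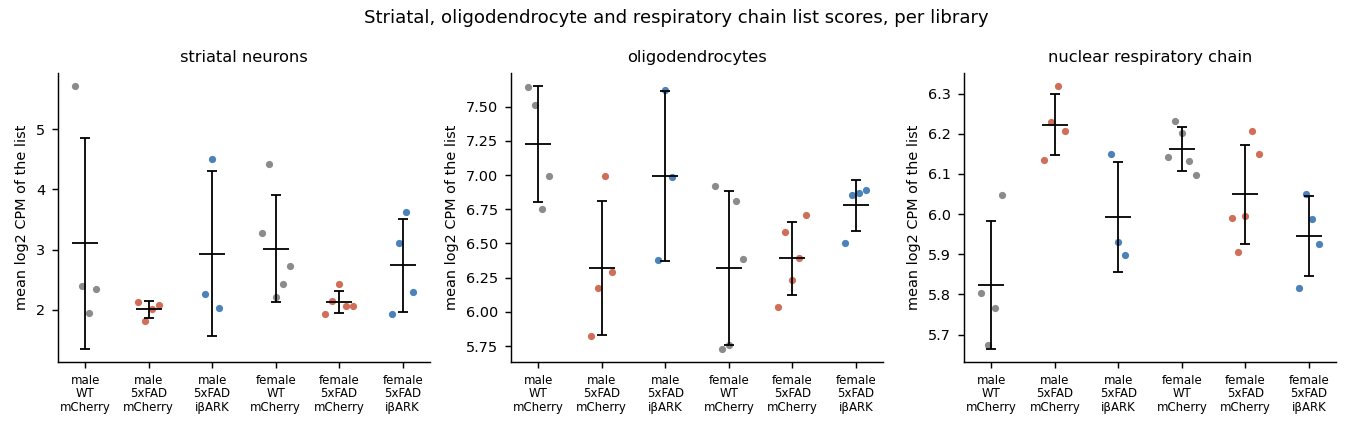
Scores of the striatal neuron, oligodendrocyte and nuclear respiratory chain lists in each library. The vertical axis is the mean log2 CPM of the list, the horizontal axis the 6 groups. Each point is 1 library, and bars are mean ± SD.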

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

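The tests of tissue makeup, of libraries rich in Igkc and of GC content and length were chosen only after the results were seen, and for Thy1 and App (library scaling included), and for blood and plaque-associated microglia, their rules were set after their own values were known.

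In 14 of 210 tests a library stood far from the others of its group, where chance alone gives about 1 in 20 groups (10.5 expected). List scores are mean log2 CPM. Antigen presentation was 3.74 in female 5xFAD mCherry replicate 1 (nearest other 2.69). The interferon response was 0.886 in male WT replicate 3 (nearest 1.58). Cytokines and chemokines were -0.694 in female WT replicate 4. Reactive astrocytes were 2.59 in male 5xFAD mCherry replicate 1 and 3.13 in female 5xFAD mCherry replicate 5. Oligodendrocytes were 6.5 in female iβARK replicate 1, endothelium 4.43 in male 5xFAD mCherry replicate 3 and choroid plexus -0.0981 in female 5xFAD mCherry replicate 3. Striatal neurons were 5.71 in male WT replicate 1. The glucocorticoid response was 4.54 in male 5xFAD mCherry replicate 1, and AAV and mechanical injury 2.44 in female WT replicate 2. Igkc was 1.31 CPM in male WT replicate 1, 10.7 in male 5xFAD mCherry replicate 4 (nearest 0.285) and 1710 in female iβARK replicate 4.

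Other values differed between groups, here the sexes, in a test of the difference itself (female minus male, edgeR). The 5xFAD effect differed in 506 genes. Tob2 (0.66), Tab2 (0.48), Snx29 (0.66) and Pcdhga8 (0.77) had the higher effect in females, and Dmac1 (-0.77), Cox14 (-0.70), Mrpl20 (-0.76), Nppc (-1.27) and Mrps18a (-0.54) the lower. The iβARK effect differed in 1 gene, Spp1 (2.96).

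Thy1 and App, read as a proxy for transgene output, were lower in iβARK than in mCherry 5xFAD mice. With oligodendrocyte and striatal scores Thy1 went from -0.76 ± 0.10 to -0.65 ± 0.10 and kept its call. App went from -0.29 ± 0.07 to -0.22 ± 0.08 and missed the threshold (edgeR adjusted p = 0.197). The rule for tissue makeup took both genes together, so tissue makeup cannot be told apart by it. Read alone, the Thy1 value goes against tissue makeup as the whole source of its fall. Library scaling is opposed by both genes, 2 of 2, staying lower and past the threshold with DESeq2 size factors and with library totals. A general loss of neuronal transcripts is opposed for Thy1 by a median of -0.18 in the glutamatergic list, and stays open for App, whose change lies within 2 SE of that median. Whether iβARK acts on the Thy1 promoter, on the cells that use it or on neither stays open, as WT mice with iβARK were not part of the design.

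Interferon, antigen presentation, lymphocyte and immunoglobulin transcripts were higher with iβARK. Red cell genes had a median of 0.53 beside 4.17 in lymphocyte genes. This opposes more blood of unchanged makeup as the whole source. Red cell genes do not measure white cells, so blood that holds more of these was not tested. The interferon signal, sexes averaged, does not rest on the 2 libraries richest in Igkc alone. Without them 25 of 30 interferon genes stayed higher and past the threshold, but only 6 of 17 lymphocyte genes did. Male iβARK replicate 2, with 269 CPM of Igkc, stayed in this test. In females the count of all genes past the threshold went from 86 to 9 without the 2 libraries. A rise of plaque-associated microglia is opposed by a median of -0.35 in their list. A reaction to the construct or vector and an effect of the peptide stay open, because no group received an inactive form of it.

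The 5xFAD effect on respiratory chain genes lay lower in females than in males (median difference -0.49, 35 of 67 genes past the threshold). With offsets for GC content and length the median moved to -0.24 and 6 genes passed, which met the rule set for such a bias only narrowly. Offsets can also remove a real change shared by genes alike in GC content and length. The test therefore leaves bias possible and does not show it as the cause. Tissue makeup cannot be told apart from a sex difference, because with oligodendrocyte and striatal scores the median stayed at -0.46 while 0 genes passed (edgeR). For ribosomal genes the median was -0.28 before and -0.07 after the offsets, and -0.39 with the scores. A biological sex difference in these genes is therefore not shown by these libraries.

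With labels redrawn at random, chance is opposed, though not excluded, where 1 split, the real one, was as large. The sex differences in effect are an exception, given below. That held for the averaged 5xFAD comparison (2095 genes, highest other 350, 1 of 100 splits), for males (2413 and 304, 1 of 35) and for females (907 and 12, 1 of 100). It also held for iβARK averaged (1157 and 365, 1 of 100) and in females (86 and 42, 1 of 100), and against WT averaged (1788 and 255, 1 of 100) and in females (1363 and 698, 1 of 100). The sexes in WT (1964 and 454, 1 of 100) stood apart in the same way. For the sex difference in the 5xFAD effect the values were 506 and 118 (1 of 100). Splits for the sex differences in effect exchanged the sexes within each condition. The sexes already differ in WT, so mixing them adds spread that can lower the redrawn counts. The low redrawn counts therefore cannot oppose chance for the sex difference in the 5xFAD effect. Chance is not opposed for iβARK in males (580 and 620, 2 of 35), for iβARK males against WT (803 and 1093, 4 of 35) or for the sex difference in the iβARK effect (1 and 40, 16 of 100). With 35 splits the smallest possible share is 2.86 percent, and the shares are not adjusted for the number of comparisons. Redrawn labels do not test what single libraries or tissue makeup add to a count. With 1 library left out, the count for iβARK in females fell as low as 1. That for the sex difference in the 5xFAD effect fell as low as 15, and to 0 with oligodendrocyte and striatal scores as covariates.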

How the results depend on the processing

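The settings that leave out libraries by striatal or Igkc content, the tissue covariates and the GC content and length offsets were chosen after seeing the data. No called value of a named gene turned its sign under any setting. Of 303 called values 9 were lost with DESeq2 size factors, 24 with library totals, 14 without a filter, 7 of 284 with the stricter filter, 0 with the DESeq2 Wald test, 19 with limma voom, 18 of 302 with only the groups compared, 86 with 1 surrogate variable, 68 without the 3 libraries richest in striatal transcripts, 13 without the 2 libraries richest in Igkc, 97 with tissue covariates and 31 with the offsets. Leaving out single libraries ended 457 of 4530 calls, over 79 values.

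The averaged 5xFAD count (2095) was 974 with 1 surrogate variable and 1129 with tissue covariates, and 1439 to 2593 with 1 library left out. In males (2413) it was 1234 with only the groups compared, 659 with 1 surrogate variable, 845 with tissue covariates and 1503 with the offsets, and 1059 to 3031 with 1 library left out. In females (907) no setting moved it by more than 1.5 times, and it was 676 to 887 with 1 library left out.

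The averaged iβARK count (1157) was 2780 with limma voom, 198 with 1 surrogate variable, 581 without the 3 striatal-rich libraries and 362 with tissue covariates, and 509 to 2206 with 1 library left out. In males (580) it was 1141 with the DESeq2 Wald test, 2495 with limma voom, 157 with only the groups compared, 16 with 1 surrogate variable, 144 without the striatal-rich libraries, 1740 without the Igkc-rich libraries and 170 with tissue covariates, and 58 to 1753 with 1 library left out. In females (86) it was 158 without a filter, 174 with the DESeq2 Wald test, 0 with limma voom, 2 with only the groups compared, 33 with 1 surrogate variable, 9 without the Igkc-rich libraries and 55 with tissue covariates, and 1 to 144 with 1 library left out. Against WT, with 1 library left out, the averaged count ran from 1347 to 2401, the male count from 457 to 1148 and the female count from 839 to 1416. The male count was 376 with limma voom and 292 with only the groups compared, and the female count reached 1859 with limma voom.

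The sex difference in the 5xFAD effect (506) was 273 without a filter, 828 with the stricter filter, 1274 with the DESeq2 Wald test, 1773 with limma voom, 177 with 1 surrogate variable, 0 without the striatal-rich libraries, 0 with tissue covariates and 80 with the offsets, and 15 to 1148 with 1 library left out. The sex difference in the iβARK effect (1) was 0 with library totals, only the groups compared, either set of libraries left out, tissue covariates or the offsets, 23 with the DESeq2 Wald test, 4 with limma voom and 2 with 1 surrogate variable, and 0 to 14 with 1 library left out. Between the sexes in WT (1964) the count was 1305 without a filter, 2957 with limma voom, 1173 with only the groups compared, 30 without the striatal-rich libraries, 9 with tissue covariates and 1209 with the offsets, and 243 to 3009 with 1 library left out.

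Of 33 lists 19 passed for the averaged 5xFAD comparison, 5 with an estimated correlation and 18 to 21 with 1 library left out. For iβARK 24 passed, 0 with an estimated correlation, 13 with fry and 23 to 26 with 1 library left out. The correlation of the 5xFAD and iβARK effects (-0.24) was -0.152 with divided libraries, -0.132 with the stricter filter, -0.0979 without the striatal-rich libraries, -0.418 without the Igkc-rich libraries and -0.198 with tissue covariates, and -0.339 to -0.167 with 1 library left out. In each case the cause was not tested.

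The replicate numbers do not pair the libraries: over 23 pairs the deviations correlated from -0.213 to 0.198, 2 of them over 0.1, and 4 of 25 libraries matched their own number best. With the replicate block the count was 312 for iβARK averaged, 47 in males, 11 in females, 517 for iβARK males against WT, 90 for the sex difference in the 5xFAD effect and 0 for that in the iβARK effect, and 67 of 303 named calls were lost. Other counts stayed within 1.5 times.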

Other observations

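The interneuron peptides and stress genes were picked for description only after the result was seen.

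In 3 of 22 genes of the GABAergic list, all of them peptide genes, the 5xFAD effect differed between the sexes, while the list itself did not pass (median -0.13, adjusted p = 0.0515). Somatostatin (Sst) fell from 275 ± 29.4 CPM in female WT to 178 ± 22.9 in female 5xFAD mCherry mice (mean ± SD) and stood at 182 ± 32.3 with iβARK, while males had 179 ± 17.6, 216 ± 29.2 and 191 ± 58.6. Tac2, the gene of neurokinin B, went from 8.97 ± 1.44 to 6.03 ± 0.906 CPM in females and from 4.87 ± 0.843 to 8.11 ± 1.03 in males, and neuropeptide Y (Npy) from 68.0 ± 10 to 53.5 ± 12.0 and from 44.7 ± 5.21 to 67.7 ± 16.4. The female minus male 5xFAD effect was -0.90 ± 0.20 for Sst (edgeR adjusted p = 0.025), -1.31 ± 0.27 for Tac2 (0.018) and -0.95 ± 0.22 for Npy (0.030). In WT all 3 were higher in females, by 0.62 ± 0.15, 0.88 ± 0.20 and 0.61 ± 0.16, so much of the difference lay in the WT mice. With GC content and length offsets the differences were -0.46 (adjusted p = 0.158), -0.99 and -0.47 (0.205), and none passed. With tissue scores none passed either (0.0938 to 0.105), though Sst stayed at -0.91 and Tac2 at -1.27. The same held without the 3 libraries richest in striatal transcripts, for Sst and Npy with the replicate block and for Npy with 1 surrogate variable. All 3 lost their calls without male WT replicate 2, male 5xFAD mCherry replicate 3 or female 5xFAD mCherry replicate 2 (0.0547 to 0.09). Sst and Npy also did so without male 5xFAD mCherry replicate 4, female WT replicates 2 and 3 or female 5xFAD mCherry replicate 1, and Npy without female WT replicate 4 or female 5xFAD mCherry replicate 3 (0.0521 to 0.0721).

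The heat shock and unfolded protein list did not pass (2 of 26 genes rose and 2 fell, median 0.06). Atf3, a transcription factor of injury, was higher in 5xFAD mCherry than in WT mice by 1.33 ± 0.26 (sexes averaged, edgeR adjusted p = 0.0013) and Sdf2l1, a folding helper of the endoplasmic reticulum, by 0.82 ± 0.13 (1.2e-04). The cytosolic heat shock genes Hspa1b and Hspa1a were lower by 0.69 ± 0.17 (0.011) and 0.49 ± 0.13 (0.021), the call of Hspa1a being lost without male WT replicate 2 (-0.38, 0.0704). The chemokine Ccl4, at 0.0300 to 0.0635 CPM in the WT group means, was higher by 4.55 ± 0.44, and the inflammasome gene Nlrp3 by 2.52 ± 0.25. Under iβARK none of Atf3, Sdf2l1, Hspa1b, Ccl4 and Nlrp3 passed (adjusted p = 0.272 to 0.961).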
